A study of Homo sapiens with 16 samples.

How the data were processed

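RNA was measured in 16 libraries of CAL51 cells at passage 10, grown in DMEM with fetal bovine serum and treated with DMSO or with CC-671 at 3 or 10 µM for 6 or 24 h. Per the labels' protocols, RNA was extracted with RNeasy kits, and strand-specific libraries from poly-A RNA were sequenced as 2 x 100 bases on a HiSeq instrument. The submitters' processing notes name STAR, HTSeq, edgeR and the human genome build hg19 (GRCh37), without versions or parameters. Each deposited file held the raw count of read pairs per gene symbol in 1 library. The strand setting, the overlap mode, the treatment of marked duplicates and the annotation release are not given in the sources used here. Genes that overlap others, antisense genes and genes known by clone names are therefore uncertain, and symbols with several loci share a value.

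Between 104609173 and 123789361 pairs per library were counted at genes. Non-gene entries of the counter made up 16.9 to 20.2% of all pairs and were kept out of library sizes and tests. Pairs outside annotated exons were 3.78 to 6.22% of all pairs, ambiguous pairs 2.55 to 2.76%, pairs without a unique alignment 10.3 to 11.9%, and pairs of low quality or without alignment 0. Between 27284 and 28952 symbols per library had a count, and 18621 of 55510 had none in any library. No library duplicated another. Groups were taken from the labels, and no sample was left out.

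Genes were kept by filterByExpr in edgeR 4.0.16 (minimum count 10, minimum total 15), which left 22007. Libraries were scaled by TMM (factors 0.963 to 1.05), and 6 group means were fitted to all libraries by robust quasi-likelihood F tests in R 4.3.3. The 9 comparisons were each dose against vehicle at each time, the doses against each other at each time, vehicle at 24 h against 6 h, and the difference between the 24 h and 6 h effects of each dose. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison, and adjusted p under 0.05 was called a change. The SE of a log2 fold change is its absolute value over the square root of F.

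Before the data were examined, the groups, comparisons, alternatives, 27 gene lists and 5 marker lists were fixed. The lists held 607 genes, of which 606 were matched, 4 by an older symbol. Lists were tested by camera in limma 3.58.1 with a preset correlation of 0.01 between genes, two-sided and adjusted over the 27 lists of a comparison. Camera with an estimated correlation and fry were alternatives. Fry asks whether the members of a list change at all, whereas camera compares them with the other genes. Ranges over the alternatives of a list include fry and leave out the estimated correlation, which is reported separately. Genes were named by rule: the 6 largest rises and 6 largest falls in comparisons with vehicle and 3 of each elsewhere, 9 genes followed throughout, and up to 4 changed members with the largest absolute values of each list described. The largest rises and falls were taken from changed genes with an average log2 CPM of at least 1 over all libraries and, except in the tests of a difference of effects, no overlap between the groups, leaving out names of small RNAs and uncharacterised loci. Members of a list outside this rule are named only where they moved against the list, and a few genes that the rule names are not reported here.

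The share of read pairs outside exons was compared between treated and vehicle libraries by an exact two-sided permutation test within times. The overlap of doses was set against 20 simulations of unchanged groups that shared the vehicle libraries. Neighbours, exon numbers and lengths were taken from GENCODE 29 on GRCh38, with gene names from the RefSeq table of GRCh38.p14. This build differs from that of the counts, so no positions are given.

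The main test was tested on simulated data of the same design with 200 planted genes, shared between 1.5-fold, 2-fold and 4-fold changes, in 21465 to 21514 genes. It recovered 86.6 to 98.5% of 1.5-fold, 97 to 100% of 2-fold and 98.5 to 100% of 4-fold changes, with 2.83 to 6.41% false calls over the 9 comparisons. A list of 20 genes with 1.3-fold changes was called in all 9, and 0 of 20 random lists were. Simulated genes were drawn independently and few were changed, so this does not test the list calls at the preset correlation.

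Alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, no scaling factor, no count filter beyond a minimum count of 1, a stricter filter of 1 CPM in 5 libraries, a fit of only the groups compared, replicate number as a block, and each library left out in turn. An alternative list test with a trend on exon number removed was added after the data were seen.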

Results

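Gene expression was measured by RNA sequencing in CAL51, an established human triple-negative breast cancer cell line, after treatment with the compound CC-671. CC-671 inhibits the kinase TTK, which acts in the spindle assembly checkpoint, and CLK2, a kinase of SR splicing factors. Cells received CC-671 at 3 or 10 µM, or its DMSO vehicle, for 6 or 24 h. Each of the 2 vehicle groups had 2 libraries and each of the 4 treated groups had 3, which gave 16 libraries in all. Between 104609173 and 123789361 read pairs per library were counted at annotated genes, and 22007 of 55510 gene symbols had enough counts to be tested. The labels call the libraries of a group biological replicates, and the p-values measure the spread between these libraries.

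Libraries of the same group correlated at r of 0.995 to 0.996 over genes and differed by more than sampling noise, with a chi-square per gene of 2.51 to 19.1. The first principal component held 53.5% of the variance and the second held 24.4%. In each comparison with vehicle, 98.4 to 99.6% of the changed genes had every treated library on the same side of both vehicle libraries. This held for 72.7 to 77.5% of all tested genes, against 20% by chance. It also held for every gene that the naming rule picked as changed against vehicle, but the rule required it of the largest rises and falls. Log2 fold changes are given ± SE from the edgeR fit. Levels are in CPM (counts scaled to the library total times its TMM factor) ± SD, with 3 treated and 2 vehicle libraries.

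**Figure D1:**
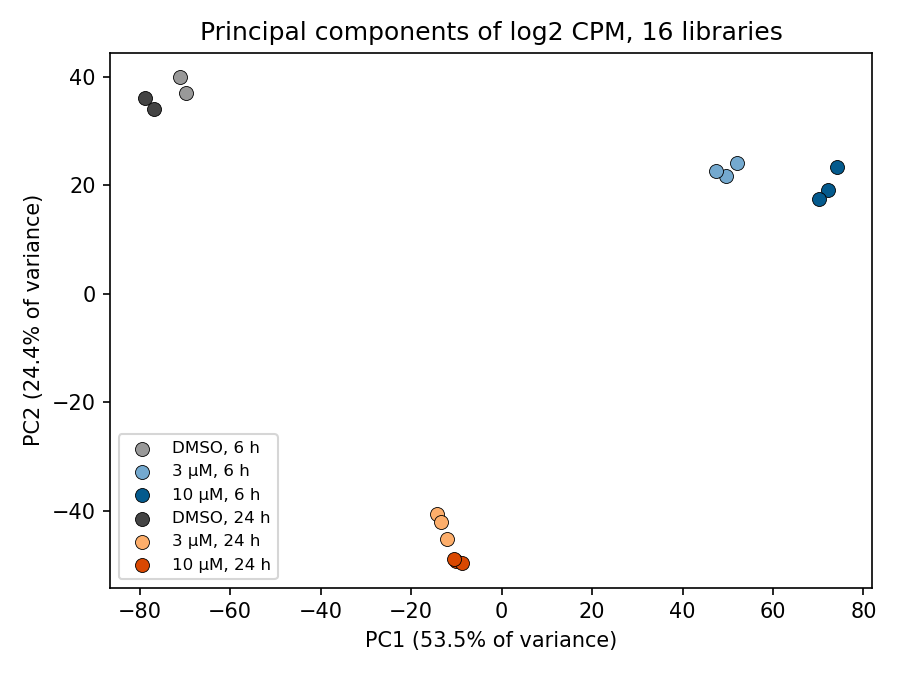
Principal components of the 16 libraries, with the first component (53.5% of variance) on the horizontal axis, the second (24.4%) on the vertical axis, and 1 point per library coloured by its group. The vehicle libraries lie between −78.8 and −69.7 on the first component, the 6 h treated libraries between 47.4 and 74.2, and the 24 h treated libraries between −14.2 and −8.66.

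To find what CC-671 changed early at the lower dose, the 3 µM libraries at 6 h were compared with vehicle at 6 h. Genes that were near silent in vehicle rose most. PTGDR2, a prostaglandin receptor, rose from 0.106 ± 0.02 to 7.99 ± 0.6 CPM (74.7-fold, log2 6.22 ± 0.15, adjusted p = 1.8e-22). CCR6, a chemokine receptor, rose 60.7-fold (5.92 ± 0.27). LTA, which encodes the cytokine lymphotoxin alpha, rose 48.6-fold (5.60 ± 0.18), and SELPLG, a selectin ligand, rose 38.5-fold (5.27 ± 0.15). DCAF4L1 rose 35.6-fold (5.15 ± 0.16), and the clone-named gene RP11-318M2.2 rose 42-fold (5.39 ± 0.18).

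The deepest falls at 3 µM and 6 h were in well expressed genes of several processes. DSCC1, a sister chromatid cohesion factor, decreased from 38.1 ± 1.3 to 5.13 ± 0.36 CPM (log2 −2.89 ± 0.05, adjusted p = 1.2e-24). UTP6, a factor of small ribosomal subunit processing, had a log2 change of −2.59 ± 0.05. The value was −2.58 ± 0.07 for PEX3, which acts in peroxisome biogenesis, and −2.46 ± 0.05 for LYRM7, an assembly factor of respiratory complex III. PRKCI, an atypical protein kinase C, changed by −2.42 ± 0.04, and the clone-named RP3-514P16.1 by −2.73 ± 0.10. In all, 13909 of 22007 genes changed at 3 µM and 6 h, 6960 higher and 6949 lower, of which 1870 rose and 1083 fell at least 2-fold. Counts of 2-fold changes, here and in the other comparisons, depended on the filter for low counts, and the stricter filter moved all 9.

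Of the kinases the compound is known to bind or their paralogs, all 5 rose at 3 µM and 6 h. CLK4 rose by 1.34 ± 0.05, CLK1 by 0.99 ± 0.04, CLK3 by 0.77 ± 0.03, TTK by 0.36 ± 0.04 and CLK2 by 0.21 ± 0.06 (list test by limma camera, adjusted p = 1.15e-05, and adjusted p = 0.0193 with an estimated correlation). The CLK2 call ended when replicate 1 of the vehicle was left out (adjusted p = 0.053, range over alternatives 0.00014 to 0.053). Of 32 p53 targets, 28 rose, 1 fell and 3 did not pass, with a median log2 change of 0.60 (adjusted p = 1.68e-12, and adjusted p = 0.202 with an estimated correlation). GDF15, a stress-induced cytokine, rose by 1.66 ± 0.09, BBC3, which encodes the cell death protein PUMA, by 1.23 ± 0.07, SESN1 by 1.22 ± 0.06 and TP53INP1 by 1.11 ± 0.04. XPC, a nucleotide excision repair factor, was the member that fell (−0.73). The cell cycle inhibitor CDKN1A rose by 1.08 ± 0.04 and MDM2, the ubiquitin ligase of p53, by 0.98 ± 0.03. Of 14 SR splicing factors, 5 rose and 8 fell (adjusted p = 0.706), with SRSF7 at −1.19 ± 0.05, SRSF10 at −0.96 ± 0.05 and TRA2B at 0.80 ± 0.03.

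Histone and ribosomal protein genes rose together at 3 µM and 6 h. Of 17 histone genes 11 rose and none fell, among them HIST1H3D by 1.80 ± 0.14 and HIST1H2BJ by 1.71 ± 0.12 (adjusted p = 2.93e-05, and adjusted p = 0.180 with an estimated correlation). Of 45 ribosomal protein genes 43 rose and none fell, by a median of 0.31, with RPL22 at 0.71 ± 0.04 and RPL15 at 0.60 ± 0.03 (adjusted p = 3.35e-08, and adjusted p = 0.889 with an estimated correlation). Members of both families share reads with near-identical copies and pseudogenes, so single values are uncertain. The libraries held poly-A RNA, so the histone counts cover only polyadenylated transcripts. Vehicle levels were low for HIST1H3D (0.445 CPM) and HIST1H2BJ (2.06 CPM). Of 25 ATF4 targets, 13 rose and 4 fell (adjusted p = 0.0234, and adjusted p = 0.940 with an estimated correlation). NUPR1, a stress-induced chromatin protein, rose by 1.48 ± 0.15, whereas SLC7A11, the cystine transporter, changed by −1.34 ± 0.14.

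DNA repair and replication genes were lower at 3 µM and 6 h. Of 20 repair genes 18 fell and none rose, with the checkpoint kinase CHEK2 at −1.41 ± 0.05 and the recombination factor XRCC2 at −1.23 ± 0.14 (adjusted p = 6.23e-06, and adjusted p = 0.345 with an estimated correlation). Of 37 E2F-driven replication genes, 10 rose and 22 fell (adjusted p = 0.029, and adjusted p = 0.889 with an estimated correlation). POLA1, the catalytic subunit of DNA polymerase alpha, changed by −1.49 ± 0.06 and the helicase factor CDC45 by −1.44 ± 0.05. Of 18 spindle checkpoint and kinetochore genes, 6 rose and 9 fell (adjusted p = 0.0217, and adjusted p = 0.889 with an estimated correlation), with SPC25 at −1.80 ± 0.05 and MAD1L1 at −1.17 ± 0.05. Of 23 cholesterol synthesis genes, 3 rose and 16 fell (adjusted p = 0.0297, and adjusted p = 0.889 with an estimated correlation), with MVD, a decarboxylase of the mevalonate pathway, at −0.88 ± 0.05. The cyclin CCNB1 rose by 0.39 ± 0.04, and MYC, at −0.20 ± 0.14, did not pass (adjusted p = 0.23).

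Adjusted over the list alone, 12 histone genes rose, 44 ribosomal protein genes rose, and 14 ATF4 targets rose and 5 fell, with the counts of the other lists at 3 µM and 6 h as given. A stricter filter on low counts ended the calls of the replication (adjusted p = 0.22), spindle checkpoint (0.163) and cholesterol lists (0.219). With a trend on exon number removed they were 0.464 for the replication and 0.783 for the spindle checkpoint list, but the list test used for this alternative did not call them before the removal either (0.176 and 0.571). The repair list kept its call in that test but went from 9.9e-05 to 0.0266. Leaving out treated replicate 1 ended the call of the cholesterol list (0.0638). Leaving aside the estimated correlation, the highest p over the alternatives of the replication, spindle checkpoint and cholesterol lists was 0.46, 0.78 and 0.22. The lowest was 7.7e-07, 8e-07 and 1e-06.

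Read pairs outside annotated exons were more frequent in the treated libraries of this time point. Their share of the pairs at genes, outside genes or at more than 1 gene was 4.57 ± 0.267% in vehicle, 5.91 ± 0.381% at 3 µM and 6.65 ± 0.378% at 10 µM. Over both times, the treated libraries exceeded vehicle by 1.58 percentage points (exact permutation test within times, two-sided, p = 0.00128, the smallest of 784 arrangements). The difference was 1.71 points at 6 h and 1.44 at 24 h, each with p = 0.0357, the smallest that the exact permutation test allows with 28 arrangements. Of 8 leukocyte marker genes tested, 5 rose and none fell at 3 µM and 6 h (median log2 change 0.76, median level 0.485 CPM), and of 7 fibroblast markers, 3 rose and 1 fell.

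**Figure D2:**
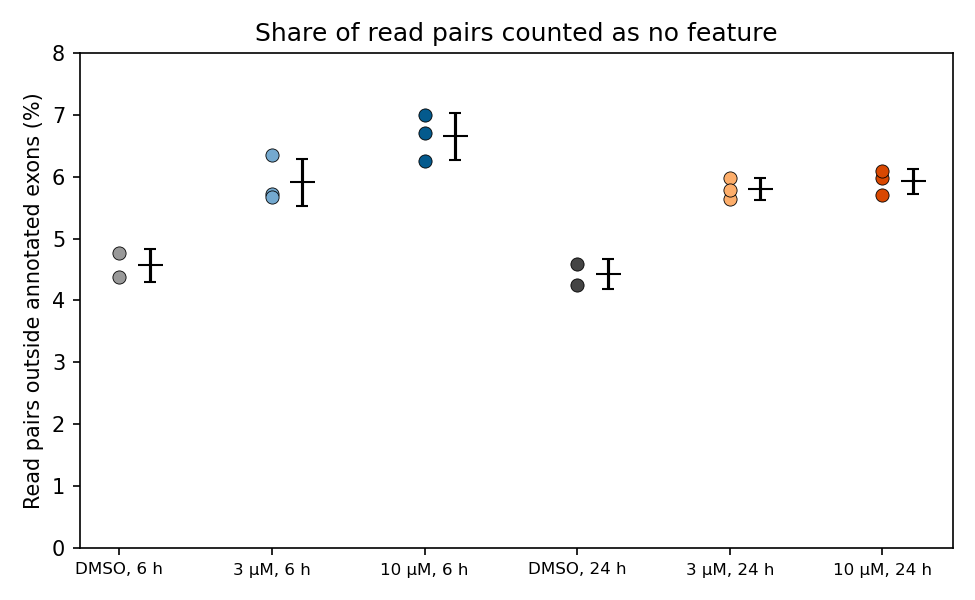
Share of read pairs outside annotated exons, in percent of pairs at genes, outside genes or at more than 1 gene, with 1 point per library and the mean ± SD of each group. Vehicle libraries lie between 4.26 and 4.76%, and treated libraries between 5.64 and 7.0%.

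The higher dose at 6 h was compared with the same vehicle libraries to find its early changes. CCR6, PTGDR2, SELPLG and DCAF4L1 were again among the largest rises. CCR6 rose from 0.0635 ± 0.0046 to 7.33 ± 1.2 CPM (113-fold, log2 6.83 ± 0.25, adjusted p = 7.5e-16), PTGDR2 rose 98.8-fold (6.63 ± 0.15) and SELPLG rose 76.6-fold (6.26 ± 0.14). DCAF4L1 rose 69-fold (6.11 ± 0.15), CMYA5, a muscle protein gene, rose 65.6-fold (6.04 ± 0.19), and RP11-372K14.2 rose 72.8-fold (6.19 ± 0.12). The deepest fall was again that of DSCC1, from 38.1 ± 1.3 to 4.64 ± 0.33 CPM (−3.03 ± 0.06, adjusted p = 2.5e-25). LYRM7 followed at −2.99 ± 0.05, PEX3 at −2.78 ± 0.07, RP3-514P16.1 at −2.76 ± 0.10, UTP6 at −2.68 ± 0.05 and PRKCI at −2.53 ± 0.04. At 10 µM and 6 h, 14870 genes changed, 7484 higher and 7386 lower, and 2362 rose and 1489 fell at least 2-fold.

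Of the 5 target kinases and paralogs, 4 rose at 10 µM and 6 h, with CLK4 at 1.35 ± 0.05, CLK1 at 1.02 ± 0.04, CLK3 at 0.76 ± 0.03 and CLK2 at 0.17 ± 0.06 (adjusted p = 0.000408, and adjusted p = 0.0773 with an estimated correlation). TTK, at 0.07 ± 0.04, did not pass (adjusted p = 0.17). The CLK2 call ended in 5 of 11 alternatives (highest adjusted p = 0.12 without vehicle replicate 1, range from 3.1e-05). It also ended without vehicle replicate 2, without treated replicate 1 or 3, and when only the compared groups were fitted. Of 32 p53 targets, 28 rose and 2 fell, by a median of 0.73 (adjusted p = 2.97e-14, and adjusted p = 0.135 with an estimated correlation). GDF15 rose by 2.26 ± 0.10, BBC3 by 1.62 ± 0.07, GADD45A, a DNA damage response gene, by 1.56 ± 0.14, CDKN1A by 1.31 ± 0.04 and MDM2 by 1.23 ± 0.03.

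Of 17 histone genes 13 rose at 10 µM and 6 h and none fell, with HIST1H3D at 2.06 ± 0.14 and HIST1H2BJ at 2.00 ± 0.11 (adjusted p = 3.24e-05, and adjusted p = 0.135 with an estimated correlation). Of 45 ribosomal protein genes 44 rose and none fell, by a median of 0.32 (adjusted p = 3.43e-07, and adjusted p = 0.731 with an estimated correlation). Stress genes rose as well. Of 25 ATF4 targets 19 rose and 4 fell, with NUPR1 at 1.94 ± 0.14 and CHAC1, a glutathione-degrading enzyme, at 1.66 ± 0.10 (adjusted p = 0.000239, and adjusted p = 0.731 with an estimated correlation). Of 17 ER chaperone genes 13 rose and 2 fell, with the chaperone HSPA5 at 1.00 ± 0.13 and HERPUD1 at 1.27 ± 0.16 (adjusted p = 0.0126, and adjusted p = 0.731 with an estimated correlation). Of 18 NF-kB and inflammatory genes 14 rose and 1 fell, by a median of 0.97, while the list test gave adjusted p = 0.0524. Its interleukins varied between libraries: IL8, a neutrophil chemokine, was at 39.3 ± 41 CPM against 3.65 ± 0.25 (3.43 ± 0.79, adjusted p = 0.0025), and IL6 rose by 2.37 ± 0.53. With only the compared groups in the fit, adjusted p was 0.111 for IL8 (range over alternatives 1.9e-07 to 0.11) and 0.109 for IL6 (range 1.9e-10 to 0.11). The list itself passed under the replicate block (adjusted p = 0.0381) and without treated replicate 1, 2 or 3 (0.00165, 0.0287 and 0.00347).

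Cell cycle genes fell more often than they rose at 10 µM and 6 h. Of 35 mitosis genes, 9 rose and 20 fell (adjusted p = 0.00191, and adjusted p = 0.731 with an estimated correlation). HMMR, a spindle-associated hyaluronan receptor, changed by −2.08 ± 0.04 and the cyclin CCNA2 by −1.47 ± 0.04, whereas CCNB1 rose by 0.23 ± 0.04. Of 18 spindle checkpoint and kinetochore genes, 4 rose and 12 fell, with SPC25 at −2.10 ± 0.05 (adjusted p = 0.000239, and adjusted p = 0.362 with an estimated correlation). Of 37 replication genes, 7 rose and 26 fell, with CDC45 at −1.61 ± 0.05 (adjusted p = 0.000319, and adjusted p = 0.494 with an estimated correlation). All 20 repair genes fell, with CHEK2 at −1.56 ± 0.05 (adjusted p = 1.68e-05, and adjusted p = 0.362 with an estimated correlation). Of 14 SR splicing factors, 5 rose and 7 fell (adjusted p = 0.939), with SRSF7 at −1.43 ± 0.05 and TRA2B at 0.87 ± 0.03. MYC was at 0.12 ± 0.14 (adjusted p = 0.45) and at −0.10 without treated replicate 1 (adjusted p = 0.0352).

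With p adjusted over the list alone, 20 ATF4 targets and 14 ER chaperone genes rose and 13 spindle checkpoint genes fell, with the counts of the other lists at 10 µM and 6 h as given. Of 8 leukocyte markers, 4 rose and 1 fell at 10 µM and 6 h, and of 7 fibroblast markers, 3 rose and 2 fell. Genes with more annotated exons had lower log2 fold changes at this dose and time (median 0.16 over 1685 genes with 2 to 4 exons and −0.41 over 463 genes with over 32). With this trend removed before the list test, adjusted p was 0.694 for the mitosis list and 0.148 for the spindle checkpoint list. The list test used for this alternative gave 0.127 and 0.0445 before the removal. The repair list, with a median of 19.5 exons, went from 8.23e-05 to 0.00889 in this test, and the replication list from 0.00873 to 0.0478. Over the alternatives other than the estimated correlation, adjusted p of the mitosis list ranged from 3.5e-06 to 0.69. That of the spindle checkpoint list ranged from 9.3e-09 to 0.15.

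To find what was changed after longer exposure, the 3 µM libraries at 24 h were compared with vehicle at 24 h. LTA rose from 0.126 ± 0.0024 to 5.35 ± 0.65 CPM (42-fold, log2 5.39 ± 0.19, adjusted p = 6.9e-17), CCR6 rose 26.9-fold (4.75 ± 0.36) and PTGDR2 rose 15.3-fold (3.93 ± 0.21). LINC00176, a long non-coding RNA, rose 24.2-fold (4.60 ± 0.19). The clone-named RP11-372K14.2 and RP11-512M8.3 rose 16.2-fold and 14.1-fold. The deepest falls were those of GADL1, a decarboxylase-like enzyme (−2.74 ± 0.10, from 5.44 ± 0.086 to 0.812 ± 0.091 CPM), and the clone-named GS1-465N13.1 (−2.61 ± 0.08). SMYD3, a lysine methyltransferase, changed by −2.33 ± 0.06, CNN1, an actin-binding calponin, by −2.21 ± 0.08 and the growth factor BMP5 by −2.20 ± 0.10.

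In all, 13339 genes changed at 3 µM and 24 h, 6529 higher and 6810 lower (48.9% higher), and 1898 rose and 560 fell at least 2-fold. Without scaling factors the median log2 change of all genes moved by 0.101 and the split became 8422 higher and 4968 lower (62.9% higher).

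p53 targets rose almost throughout at 3 µM and 24 h. Of 32, 31 rose and 1 fell, by a median of 1.08 (adjusted p = 7.46e-49, and adjusted p = 0.00543 with an estimated correlation). GDF15 rose by 2.74 ± 0.10, FDXR, a mitochondrial ferredoxin reductase, by 2.04 ± 0.05, CDKN1A by 1.96 ± 0.04 (from 57.7 ± 0.55 to 225 ± 6.5 CPM) and MDM2 by 1.32 ± 0.03, while the kinase PLK2 was the member that fell (−0.25). Of 25 ATF4 targets 23 rose and 2 fell, by a median of 0.97 (adjusted p = 1.7e-30, and adjusted p = 0.0315 with an estimated correlation). NUPR1 rose by 3.80 ± 0.12, the pseudokinase gene TRIB3 by 2.62 ± 0.26 and CHAC1 by 2.57 ± 0.11. Of 23 cholesterol synthesis genes 22 fell and none rose, by a median of −0.54 (adjusted p = 3.81e-20, and adjusted p = 0.0103 with an estimated correlation). The lanosterol synthase LSS changed by −1.02 ± 0.03 and the squalene epoxidase SQLE by −0.91 ± 0.04. Of the target kinases 4 rose, with CLK3 at 1.02 ± 0.03, CLK4 at 0.93 ± 0.05, CLK1 at 0.79 ± 0.04 and CLK2 at 0.54 ± 0.06 (adjusted p = 1.87e-06, and adjusted p = 0.00543 with an estimated correlation), while TTK was at −0.06 ± 0.04 (adjusted p = 0.22).

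Of 35 mitosis genes, 1 rose and 27 fell at 3 µM and 24 h (adjusted p = 8.53e-07, and adjusted p = 0.388 with an estimated correlation). CCNA2 changed by −0.70 ± 0.04, the kinesin KIF11 by −0.64 ± 0.04 and CCNB1 by −0.41 ± 0.04. Of 18 spindle checkpoint genes 13 fell, with SPC24 at −0.93 ± 0.04 (adjusted p = 0.00155, and adjusted p = 0.349 with an estimated correlation). Of 14 SR splicing factors, 2 rose and 10 fell, with SRSF10 at −0.65 ± 0.05 and SRSF12 at 0.59 ± 0.06 (adjusted p = 0.00847, and adjusted p = 0.286 with an estimated correlation). Of 20 hnRNP genes, 2 rose and 16 fell, with HNRNPD at −0.61 ± 0.03 (adjusted p = 0.00491, and adjusted p = 0.388 with an estimated correlation). Of 19 lysosome and autophagy genes 15 rose, with GPNMB, a lysosomal membrane glycoprotein, at 1.27 ± 0.08 and GABARAPL1 at 0.94 ± 0.06 (adjusted p = 4.6e-05, and adjusted p = 0.286 with an estimated correlation). Of 29 oxidative phosphorylation genes, 2 rose and 17 fell, with the complex III subunit UQCRC2 at −1.02 ± 0.03 (adjusted p = 0.0441, and adjusted p = 0.700 with an estimated correlation). Of 23 interferon response genes, 15 rose and 4 fell (adjusted p = 0.0467, and adjusted p = 0.337 with an estimated correlation), with the antiviral enzyme RSAD2 at 1.59 ± 0.35 and OASL at 2.10 ± 0.71. The OASL call ended with DESeq2 (adjusted p = 0.0533) and without vehicle replicate 2. OASL lay at only 0.0138 ± 0.0056 CPM in the 24 h vehicle.

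Adjusted over the list alone, 2 mitosis genes rose at 3 µM and 24 h, with the counts of the other lists as given. A stricter filter on low counts ended the calls of the SR factors (adjusted p = 0.0783), hnRNP genes (0.0704), interferon response (0.12) and oxidative phosphorylation (0.194). Each was the highest over the alternatives other than the estimated correlation, with the lowest at 1.4e-07, 4.6e-07, 3.5e-06 and 0.00061. The interferon call also ended under the replicate block (0.0501), without vehicle replicate 1 (0.0558) and without treated replicate 2 (0.0574). That of oxidative phosphorylation ended without vehicle replicate 1 (0.0615) and without treated replicate 1 (0.0506). Without scaling factors, 4 hnRNP genes rose and 10 fell, 3 spindle checkpoint genes rose and 8 fell, and 7 oxidative phosphorylation genes rose and 8 fell. All 7 fibroblast markers tested fell at 3 µM and 24 h (median −0.80, median level 12.4 CPM against 21.6 in vehicle), and 4 leukocyte markers rose and 2 fell. The share of read pairs outside exons was 5.80 ± 0.171% at 3 µM and 5.93 ± 0.203% at 10 µM, against 4.42 ± 0.238% in vehicle at 24 h.

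The 10 µM libraries at 24 h were compared with the same vehicle. LTA rose from 0.126 ± 0.0024 to 6.84 ± 0.34 CPM (53.7-fold, log2 5.75 ± 0.19, adjusted p = 7.2e-18), LINC00176 and CCR6 each rose 26.5-fold (4.73 ± 0.19 and 4.73 ± 0.36), and NUPR1 rose 23.1-fold (4.53 ± 0.12). RP11-372K14.2 rose 26-fold and RP11-512M8.3 rose 18-fold. GADL1 fell from 5.44 ± 0.086 to 0.637 ± 0.049 CPM (−3.10 ± 0.10, adjusted p = 1.2e-19), followed by GS1-465N13.1 (−2.82 ± 0.08), SMYD3 (−2.64 ± 0.06), BMP5 (−2.58 ± 0.10) and CNN1 (−2.45 ± 0.08). In all, 14005 genes changed at 10 µM and 24 h, 6891 higher and 7114 lower (49.2% higher), and 2054 rose and 807 fell at least 2-fold. Without scaling factors the median of all genes moved by 0.111 and the split became 8790 higher and 5322 lower (62.3% higher).

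Of 32 p53 targets, 31 rose and 1 fell at 10 µM and 24 h, by a median of 1.11 (adjusted p = 1.9e-41, and adjusted p = 0.0128 with an estimated correlation). GDF15 rose by 3.10 ± 0.10, FDXR by 2.00 ± 0.05, GADD45A by 1.93 ± 0.15, CDKN1A by 1.91 ± 0.04 and MDM2 by 1.38 ± 0.03. Of 25 ATF4 targets, 23 rose and 1 fell (adjusted p = 9.72e-30, and adjusted p = 0.0343 with an estimated correlation), with TRIB3 at 2.96 ± 0.26 and the transcription factor ATF3 at 2.85 ± 0.68. Of 23 cholesterol synthesis genes, 1 rose and 20 fell, with LSS at −1.05 ± 0.03 and SQLE at −0.92 ± 0.04 (adjusted p = 2.62e-15, and adjusted p = 0.0258 with an estimated correlation). Of the target kinases 4 rose and 1 fell (adjusted p = 2.65e-05, and adjusted p = 0.0128 with an estimated correlation), with CLK3 at 1.05 ± 0.03, CLK4 at 0.93 ± 0.05, CLK1 at 0.77 ± 0.04 and CLK2 at 0.56 ± 0.06. TTK changed by −0.13 ± 0.04 (adjusted p = 0.014), a call that ended without scaling factors (−0.01, adjusted p = 0.771) and without vehicle replicate 1 (0.091) or treated replicate 2 (0.059), with a lowest p of 6.3e-05. Of 19 lysosome and autophagy genes 17 rose and none fell, with GPNMB at 2.08 ± 0.08 and GABARAPL1 at 1.14 ± 0.06 (adjusted p = 6.37e-09, and adjusted p = 0.0884 with an estimated correlation).

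Most tested mitosis, replication, SR factor and hnRNP genes fell at 10 µM and 24 h. Of 35 mitosis genes, 1 rose and 29 fell, with CCNA2 at −0.86 ± 0.04, KIF11 at −0.80 ± 0.04 and CCNB1 at −0.52 ± 0.04 (adjusted p = 3.67e-10, and adjusted p = 0.239 with an estimated correlation). Of 18 spindle checkpoint genes 14 fell, with SPC24 at −1.10 ± 0.04 (adjusted p = 0.000188, and adjusted p = 0.239 with an estimated correlation). Of 37 replication genes, 7 rose and 24 fell, with POLA1 at −0.99 ± 0.05 and the ribonucleotide reductase subunit RRM2 at −0.95 ± 0.03 (adjusted p = 0.0130, and adjusted p = 0.506 with an estimated correlation). Of 14 SR factors, 2 rose and 10 fell, with SRSF10 at −0.78 ± 0.05 (adjusted p = 0.000917, and adjusted p = 0.139 with an estimated correlation). Of 20 hnRNP genes, 2 rose and 16 fell, with HNRNPD at −0.76 ± 0.03 (adjusted p = 0.000545, and adjusted p = 0.239 with an estimated correlation). Of 29 oxidative phosphorylation genes, 1 rose and 18 fell, with UQCRC2 at −1.29 ± 0.03 (adjusted p = 0.00437, and adjusted p = 0.614 with an estimated correlation). MYC, at −0.04 ± 0.14, did not pass (adjusted p = 0.83).

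The counts of the lists given here at 10 µM and 24 h (p53 and ATF4 targets, cholesterol, kinases, lysosome, mitosis, spindle checkpoint, replication, SR, hnRNP and oxidative phosphorylation) were the same adjusted over the list alone. The stricter filter ended the calls of the replication genes (adjusted p = 0.126) and oxidative phosphorylation (0.0561). Over the alternatives other than the estimated correlation, their adjusted p ranged from 1.1e-06 to 0.13 and from 3.3e-05 to 0.056. Without scaling factors these lists had 11 higher and 15 lower and 6 higher and 13 lower. All 7 fibroblast markers fell (median −0.80), 3 of 5 endothelial markers fell and none rose (median −0.34), and 3 leukocyte markers rose and 3 fell.

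**Figure D3:**
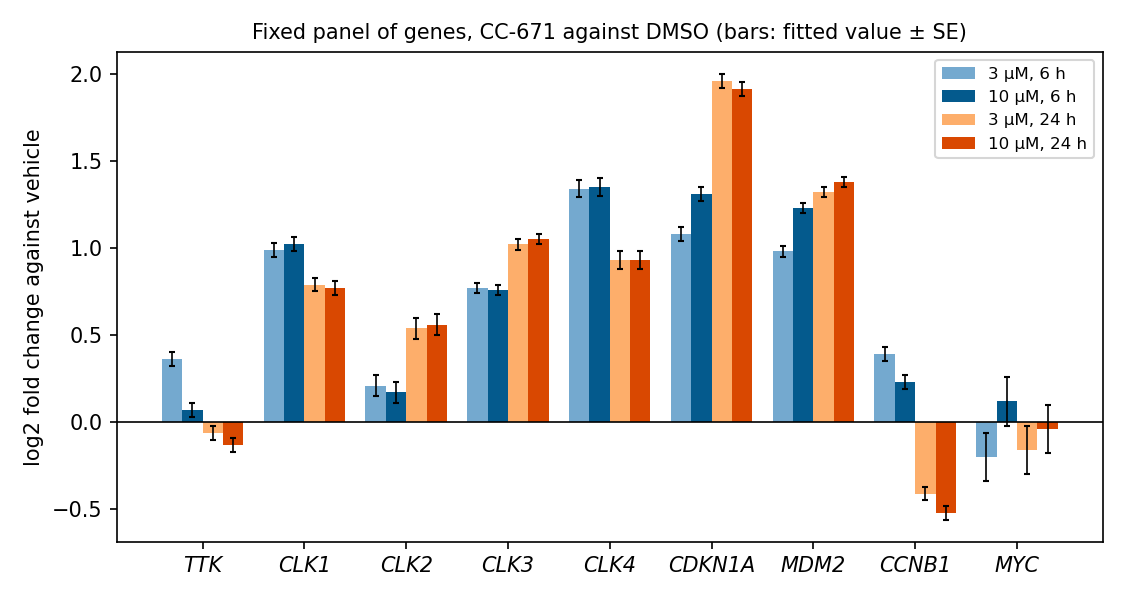
Log2 fold change against vehicle (vertical axis) of the 9 genes followed in every comparison, with 1 bar per dose and time and error bars of ± 1 SE. CDKN1A reaches 1.96 ± 0.04 at 3 µM and 24 h, CLK4 1.35 ± 0.05 at 10 µM and 6 h, and CCNB1 goes from 0.39 ± 0.04 at 3 µM and 6 h to −0.52 ± 0.04 at 10 µM and 24 h.

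**Figure D4:**
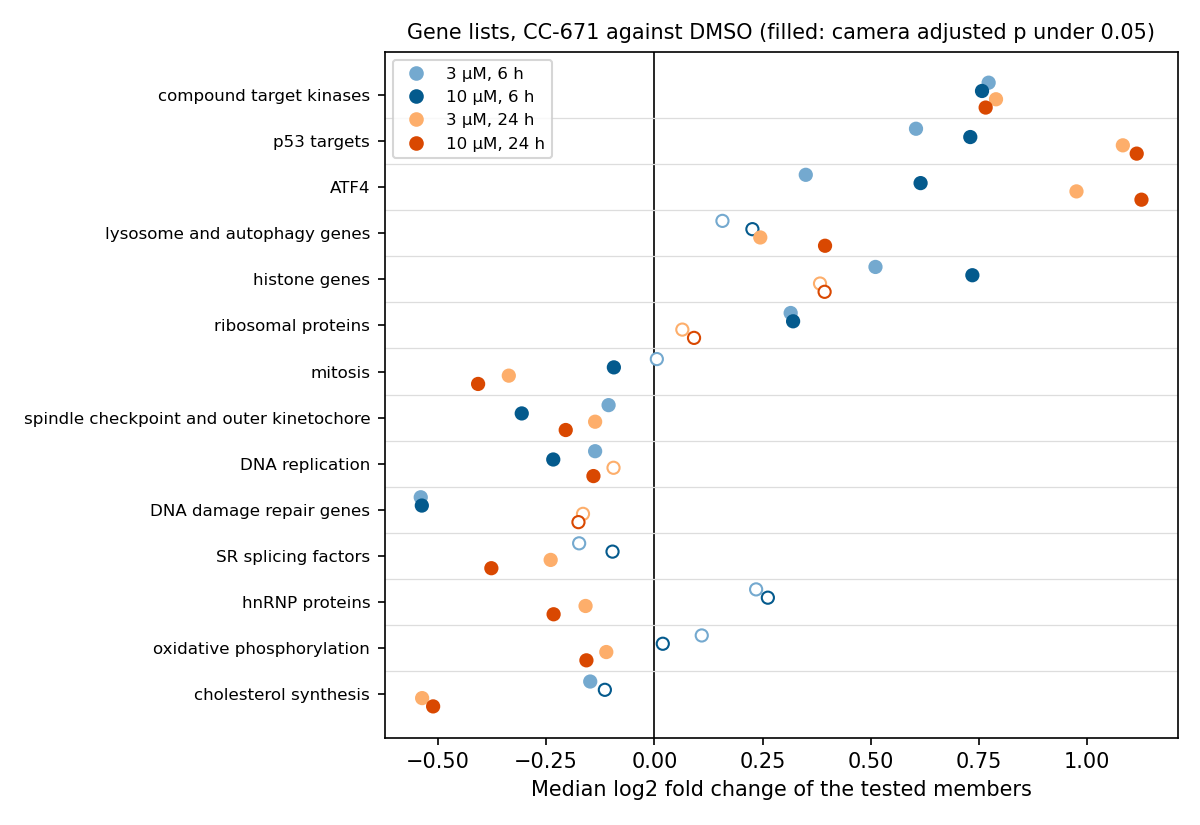
Median log2 fold change against vehicle of 14 gene lists in the 4 comparisons, with filled points where the camera adjusted p was under 0.05. The median of the p53 targets is 0.60 and 0.73 at 6 h and 1.08 and 1.11 at 24 h, and that of the cholesterol synthesis genes is −0.54 and −0.51 at 24 h.

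With the estimated correlation, 1 of 9 list calls held at 3 µM and 6 h, 0 of 10 at 10 µM and 6 h, and 4 of 11 at each dose at 24 h (p53 targets, ATF4 targets, cholesterol synthesis and target kinases). The lowest adjusted p with an estimated correlation at 10 µM and 6 h was 0.0773, against 0.000408 with the preset one, and fry called more lists than camera. None of the lists called by camera in the text has a median, mean and test of different sign.

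The doses were compared directly to find what depended on dose. At 6 h, the ATF4, ER chaperone and p53 lists were higher and the mitosis and replication lists lower at 10 µM than at 3 µM. Camera called 18 of 27 lists in this comparison, of which 8 are given here. With an estimated correlation 0 held (lowest adjusted p = 0.109). Of 25 ATF4 targets 20 were higher (adjusted p = 2.66e-11, and adjusted p = 0.190 with an estimated correlation), and of 17 ER chaperone genes 13 (adjusted p = 8.91e-08, and adjusted p = 0.252 with an estimated correlation). When only the compared groups were fitted, the calls ended for the ATF4 targets ATF3, TRIB3, DDIT3 and STC2 and the ER genes DERL3, HERPUD1, DNAJB9 and HSPA5, the largest of each list (adjusted p = 0.0533 for STC2 to 0.231 for ATF3, with the lowest over alternatives from 1.7e-12 for STC2 to 0.0019 for DERL3). Of 32 p53 targets, 17 were higher and 2 lower, with GDF15 at 0.60 ± 0.08 (adjusted p = 3.92e-10, and adjusted p = 0.166 with an estimated correlation). Of 35 mitosis genes 23 were lower, with CCNA2 at −0.52 ± 0.04 and HMMR at −0.47 ± 0.04 (adjusted p = 6.8e-20, and adjusted p = 0.109 with an estimated correlation), and of 37 replication genes 22 were lower and 2 higher, with CHAF1B at −0.45 ± 0.03 (adjusted p = 1.85e-10, and adjusted p = 0.109 with an estimated correlation). Of 18 NF-kB genes 9 were higher (adjusted p = 4.66e-05, and adjusted p = 0.407 with an estimated correlation), of 13 YAP targets 7, with LATS2 at 0.26 ± 0.03 (adjusted p = 0.000356, and adjusted p = 0.252 with an estimated correlation), and of 15 BCL2 family genes 8 were higher and 1 lower, with BBC3 at 0.39 ± 0.05 (adjusted p = 0.00318, and adjusted p = 0.109 with an estimated correlation). When p was adjusted over the list alone, 27 mitosis genes were lower and 1 higher, 26 replication genes lower and 3 higher, and 20 p53 targets, 21 ATF4 targets (1 lower), 14 NF-kB genes and 10 BCL2 family genes higher.

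Single genes with the largest dose differences at 6 h were IL8 (2.24 ± 0.61), ATF3 (1.63 ± 0.47) and IL6 (1.54 ± 0.43) among those higher, and the alarmin IL33 (−0.73 ± 0.10), the hydroxylase HIF1AN (−0.66 ± 0.05) and ARMCX2 (−0.65 ± 0.06) among those lower. The calls of IL8, ATF3 and IL6 ended when only the compared groups were fitted (adjusted p = 0.205, 0.231 and 0.214, the highest over their alternatives, with the lowest at 0.00074, 9e-07 and 6.9e-05). Those of ATF3 and IL6 also ended without any 1 of the 3 µM libraries, and that of IL8 without 3 µM replicate 2 or 3. TTK was lower at 10 µM (−0.29 ± 0.04) and CDKN1A and MDM2 were higher (0.23 and 0.25), while CLK1 to CLK4 did not pass (adjusted p = 0.55 to 0.93). In all, 5480 genes differed between the doses at 6 h, 2649 higher and 2831 lower at 10 µM, 173 and 27 of them at least 2-fold, and 3420 with only the 6 libraries compared.

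At 24 h, camera called 13 of 27 lists between the doses, of which 5 are given here, and 1 held with an estimated correlation. Lysosome and autophagy genes were higher at 10 µM than at 3 µM. Of 19, 15 were higher and none lower, with GPNMB at 0.81 ± 0.06, WIPI1 at 0.42 ± 0.06 and the sialidase NEU1 at 0.37 ± 0.04 (adjusted p = 3.17e-25, and adjusted p = 0.0136 with an estimated correlation). Of 35 mitosis genes 17 were lower, with UBE2C at −0.20 ± 0.03 (adjusted p = 1.9e-17, and adjusted p = 0.166 with an estimated correlation), of 37 replication genes 12, with E2F8 at −0.20 ± 0.03 (adjusted p = 6.83e-13, and adjusted p = 0.0978 with an estimated correlation), and of 14 SR factors 5, with TRA2A at −0.27 ± 0.03 (adjusted p = 3.13e-05, and adjusted p = 0.0978 with an estimated correlation). Of 25 ATF4 targets 3 were higher, NUPR1 by 0.73 ± 0.07 (adjusted p = 2.8e-09, and adjusted p = 0.249 with an estimated correlation). The call of this list also ended with fry (0.0501, range over the alternatives other than the estimated correlation 9.8e-10 to 0.05). Adjusted over the list alone, 17 lysosome genes were higher, 26 mitosis and 19 replication genes lower, 8 SR factors lower and 2 higher, and 8 ATF4 targets higher. RP11-372K14.2 was higher (0.68 ± 0.07), and DPYSL5, H19 and TUBA4A were lower (−0.57 ± 0.10, −0.47 ± 0.12 and −0.46 ± 0.08), of which H19, an imprinted non-coding RNA, lost its call without 1 of 3 libraries (adjusted p up to 0.145, range from 0.0089). Of the followed genes only CCNB1 passed (−0.11, adjusted p = 0.034), and without any 1 of the 6 libraries it did not (0.0521 to 0.173).

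In all, 1397 genes differed between the doses at 24 h, 549 higher and 848 lower at 10 µM (39.3% higher), 12 of them at least 2-fold. Without scaling factors the split was 732 higher and 725 lower (50.2% higher). With only the 6 libraries compared 3753 genes differed, and without 1 library 654 to 858 did. Of 7 fibroblast markers, 2 were lower at 10 µM and none higher.

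The effects of the doses were set side by side over 22007 genes. At 6 h their log2 fold changes correlated at r = 0.968 over genes, which are not independent replicates, against 0.605 for simulated unchanged groups sharing the same vehicle libraries. Their covariance was 1.01 against a simulated 0.0631, a difference of 0.945. The edgeR test called 6296 genes higher and 6407 lower at both doses, where independent lists would share 2367 and 2332 and the simulations gave means of 0.5 and 0.35, and 16 genes were called in opposite directions. At 24 h the correlation was 0.961 against 0.635, the covariance 0.652 against 0.07 (difference 0.582), and 5995 genes were higher and 6351 lower at both doses, against 2044 and 2201. Sharing the vehicle libraries gave a covariance of only 0.0631 at 6 h and 0.07 at 24 h in the simulations. This argues against the spread of the shared controls as the source of the excess. A check with separate controls was not possible, since 2 vehicle libraries cannot be divided into separate groups of 2.

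Vehicle libraries at 24 h were compared with those at 6 h to measure what time in culture changed by itself. Of 23 cholesterol synthesis genes 21 were higher at 24 h and none lower, with INSIG1 at 0.56 ± 0.05 and HMGCS1 at 0.50 ± 0.04 (adjusted p = 8.66e-40, and adjusted p = 0.00203 with an estimated correlation). SCD, a fatty acid desaturase, and IL33 were each higher by 0.98 (± 0.04 and ± 0.10), as was the clone-named RP11-325F22.5 (0.96 ± 0.09), while IL32 (−1.08 ± 0.06), the cardiac troponin gene TNNT2 (−0.96 ± 0.11) and the neuropeptide gene GAL (−0.91 ± 0.09) were lower. Of 13 YAP targets, 1 was higher and 9 lower, with the matricellular protein genes CYR61 at −0.77 ± 0.14 and CTGF at −0.58 ± 0.09 (adjusted p = 9.36e-08, and adjusted p = 0.240 with an estimated correlation). Of 45 ribosomal protein genes 32 were lower, with RPS16 at −0.26 ± 0.04 (adjusted p = 5.65e-14, and adjusted p = 0.658 with an estimated correlation), and of 16 heat shock genes 7 were lower, with HSPA8 at −0.30 ± 0.04 (adjusted p = 0.000447, and adjusted p = 0.658 with an estimated correlation). Of 7 fibroblast markers, 6 were higher and 1 lower. There were 22 cholesterol genes higher, and 10 YAP targets and 36 ribosomal protein genes lower, adjusted over the list alone. CDKN1A was lower (−0.17, adjusted p = 0.0076), a call that ended without 6 h replicate 2 (0.091, range over alternatives 0.0022 to 0.091) or 24 h replicate 1 (0.0709), and MYC, at −0.46 ± 0.15, did not pass (adjusted p = 0.057). Between the vehicle groups 4522 genes changed, 2421 higher and 2101 lower, 104 of them at least 2-fold, and without any 1 of the 4 libraries 2604 to 3579 did.

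The effect of each dose at 24 h was tested against its effect at 6 h. It differed for 10853 genes at 3 µM, 5631 with a higher and 5222 with a lower log2 fold change at 24 h, and for 11883 at 10 µM, 6068 higher and 5815 lower. Without scaling factors the shares with a higher value moved from 51.9 to 61.9% and from 51.1 to 61.3%. ATF4 targets had higher effects at 24 h, 21 of 25 at 3 µM and 18 at 10 µM (adjusted p = 1.99e-13 and 3.68e-07, and adjusted p = 0.345 and 0.417 with an estimated correlation). Asparagine synthetase ASNS differed by 1.86 ± 0.06 and 1.80 ± 0.06. Of 32 p53 targets, 21 and 17 had higher effects (adjusted p = 9.01e-07 and 0.00591, and adjusted p = 0.385 and 0.700 with an estimated correlation), with FDXR at 1.69 ± 0.07 and 1.54 ± 0.07. Of 20 repair genes, 15 and 13 had higher effects (adjusted p = 0.000554 and 0.00259, and adjusted p = 0.447 and 0.556 with an estimated correlation). Of 23 cholesterol synthesis genes, 17 had lower effects at 24 h at each dose (adjusted p = 1.65e-07 and 3.04e-05, and adjusted p = 0.345 and 0.368 with an estimated correlation). Adjusted over the list alone, these counts were the same except for 16 and 14 repair genes.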

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

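The effect of CC-671 at 24 h differed from its effect at 6 h by the test of the difference for every result in the first paragraphs, and among the later tests of explanations those of CPM gained by leukocyte markers, isolated receptors, an even spread and gain per kb were chosen after values were seen.

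At 3 µM the effects at the times differed for 10853 genes. RP3-514P16.1 (2.57), the cystine transporter SLC7A11 (2.34) and the stress gene NUPR1 (2.32) had the most positive differences, and RP11-318M2.2 (−3.89), the selectin ligand SELPLG (−3.65) and the muscle gene CMYA5 (−3.23) the most negative. TTK differed by −0.42, CLK1 by −0.20, CLK2 by 0.32, CLK3 by 0.25, CLK4 by −0.42, CDKN1A by 0.89, MDM2 by 0.34 and the cyclin CCNB1 by −0.80. The CLK1 difference was lost in 2 of 16 alternatives (adjusted p 0.0021 to 0.082).

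At 10 µM they differed for 11883 genes, with RP3-514P16.1 at 2.64, NUPR1 at 2.58 and the clone-named AC083799.1 at 2.53, and with SELPLG at −4.64, RP11-318M2.2 at −4.41 and CMYA5 at −3.61. TTK differed by −0.19, CLK1 by −0.26, CLK2 by 0.39, CLK3 by 0.29, CLK4 by −0.42, CDKN1A by 0.60, MDM2 by 0.15 and CCNB1 by −0.76. The difference of TTK was lost without scaling factors (adjusted p = 0.16, range 0.0028 to 0.16), and that of MDM2 without 6 h vehicle replicate 2 (0.08, adjusted p = 0.15, range 2e-05 to 0.15).

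The list medians of the difference at 3 µM were 0.78 for ATF4 targets, 0.39 for interferon response, 0.35 for p53 targets and 0.31 for repair genes. They were −0.46 for cholesterol synthesis, −0.34 for histones, −0.29 for ER chaperones, −0.25 for hnRNP genes, −0.25 for ribosomal proteins, −0.23 for mitosis and −0.17 for oxidative phosphorylation. Of 45 ribosomal protein genes 39 had lower effects at 24 h (40 adjusted over the list alone), as did 13 of 20 hnRNP genes, 9 of 17 histones, 8 of 17 ER chaperones, 19 of 35 mitosis genes (20 adjusted over the list alone) and 18 of 29 oxidative phosphorylation genes (19 adjusted over the list alone). Of 23 interferon genes 12 had higher effects, with IRF7, a transcription factor, at 1.15 ± 0.09. None of these 11 calls held with an estimated correlation (lowest adjusted p = 0.345), and the stricter filter ended those of ER chaperones, interferon and oxidative phosphorylation (0.0719 each, with the lowest at 0.0089, 1e-05 and 0.0089). The interferon call ended in 7 of 14 alternatives other than the estimated correlation, among them the replicate block (0.0503) and the loss of any 1 of 5 libraries. That of oxidative phosphorylation also ended without 6 h vehicle replicate 2 or without 6 h treated replicate 3 (0.0593).

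At 10 µM the medians were 0.61 for ATF4 targets, 0.39 for interferon response, 0.29 for repair genes, 0.23 for p53 targets and 0.16 for lysosome genes. They were −0.56 for ER chaperones, −0.51 for histones, −0.41 for cholesterol synthesis, −0.32 for hnRNP genes, −0.26 for ribosomal proteins and −0.15 for SR factors. The splicing regulators TRA2A (−1.22 ± 0.05) and TRA2B (−1.21 ± 0.05) had lower effects at 24 h, while SRSF5 (0.88 ± 0.18) and SRSF7 (0.78 ± 0.07) had higher ones. Of 19 lysosome genes 12 had higher effects and none lower, with GPNMB at 1.61 ± 0.12. None of the 11 calls held with an estimated correlation (lowest adjusted p = 0.368), and the stricter filter ended that of lysosome genes (0.058, range over the other alternatives 1.4e-05 to 0.058).

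Many near-silent genes rose at 6 h: of 6488 tested genes under 0.5 CPM in vehicle, 77 fell and 1083 rose at least 4-fold at 10 µM, of which 817 also rose at 3 µM and 475 at 24 h. The risen genes had a median of 0.0296 CPM in the 6 h vehicle. The count filter could keep genes that low through their treated libraries, and they had little room to fall. The excess of rises over falls is therefore partly built in by the filter. An expressed gene upstream on the same strand, within 50 kb by GENCODE 29, was found for 54.4% of 579 risen symbol-named genes and 28.9% of 2884 others (odds ratio 2.94, 95% interval 2.45 to 3.53, Fisher exact two-sided p = 6.7e-31), against an odds ratio of 1.22 on the opposite strand, so read-through from such genes may explain part of the rises. Lying inside an expressed gene (odds ratio 1.21, interval 0.889 to 1.65, by a rule restated after the value was seen) was excluded as the whole cause. The gains of leukocyte markers argued against RNA from leukocytes as the whole cause, while the planned median of 8 markers (0.77, interval −0.11 to 2.45) left it open. The 11 markers under 0.5 CPM in vehicle gained a median of 0.00774 CPM (interval to 0.212), against 0.263 (interval from 0.236) for all risen genes. Among these markers CD52 went from 0.224 to 0.225, LAPTM5 from 0.148 to 0.138 and CD14 from 0.152 to 2.77. The 13 markers together gained 2.14 ± 0.358 CPM, against 38.8 ± 1.38 for SELPLG, CCR6, LTA and PTGDR2. The genes they were compared with were selected for their rise, and these comparisons were chosen after values were seen. Diffuse background stays open, since summed olfactory receptor CPM rose by a ratio of 2.85, past the 2-fold planned for it, and a median gain of 0.153 CPM per kb of exon in the risen genes, against 0.00103 in receptors, would exclude only an even background and comes from genes selected for their rise.

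The share of pairs outside exons was higher in treated libraries. Olfactory receptor genes, which are mostly silent outside the olfactory epithelium, rose by a summed ratio of 2.85 ± 0.225 at 6 h and 1.47 ± 0.235 at 24 h at 10 µM, against share ratios of 1.46 and 1.34, and by 2.17 ± 0.307 and 1.65 ± 0.332 where no expressed gene lay within 100 kb. This is what genomic DNA or diffuse background was planned to show, so it may be a source of the extra pairs. The isolated receptors gained 0.248 ± 0.0647 CPM at 6 h and 0.133 ± 0.0639 at 24 h, less than the 0.931 and 0.493 of an even spread over the genome, but that profile was assumed and the comparison excludes nothing. Intron-retaining RNA could not be decided: 38 sense intronic genes minus 282 lincRNAs differed by −0.14 (95% interval −0.56 to 0.28, two-sided permutation p = 0.583), which met the bound written beforehand but not by more than its spread.

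Genes with more exons had lower effects at 6 h (Spearman −0.353 at 10 µM and −0.383 at 3 µM over 12250 genes), with −0.123 at 10 µM and −0.113 at 3 µM at 24 h and 0.310 between the vehicle groups, a pattern found by looking at exon number, lengths, intron density, abundance and gene type before the tests were written. The correlation was −0.297 given transcript length (interval −0.315 to −0.281) and −0.254 given gene body length (−0.270 to −0.237), so neither length is the whole cause. The steepest slope between libraries of a group was 0.0372 per doubling of exon number over 14 pairs, against −0.138 for the effect at 10 µM and 6 h. Variation between libraries of a group was thus smaller than this effect. Such pairs cannot show differences between groups, and the slope between the vehicle groups was 0.0368. At 24 h the slopes of the effect were −0.0336 at 3 µM and −0.0417 at 10 µM, close to the steepest slope within a group.

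For the doses, relabelling the 6 libraries gave 3420 genes for the real split at 6 h and 0 for the highest other, and 3753 and 0 at 24 h, with the real split 1 of 10, and 10 splits are too few for a share under 0.05.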

How the results depend on the processing

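Every alternative named in the methods was run, and among these tests only the list test with an exon-number trend removed was chosen after results were seen. The 1 gene result that reversed was MYC at 10 µM and 6 h, which did not pass in the main test (0.12) and was lower without treated replicate 1 (−0.10, adjusted p = 0.0352), with −0.10 to 0.23 over the libraries left out. No named gene called in the main test turned, and the medians that changed sign without scaling factors were those of core spliceosome, BCL2 family and mesenchymal genes at 24 h, none of them called there. Of 512 named gene results 483 were called, and 58 lost the call under some alternative, as did 5 of 80 called list results with a library left out. Counts of genes changed at least 2-fold moved beyond the margin set for a stable count in 9 of 9 comparisons under the stricter filter. They did so in 3 of 9 with DESeq2, in 1 of 9 with the replicate block and in 7 of 56 fits with a library left out. All 9 stayed within it with limma-voom, RLE scaling or no count filter. Fitting only the groups compared gave 3420 genes between the doses at 6 h (5480 in the main test) and 3753 at 24 h (1397). The main test took 1 spread per gene from all 16 libraries. Libraries of a treated group differed more at 6 h (chi-square per gene 6.54 to 19.1) than at 24 h (2.51 to 6.32). The main counts of dose differences at 6 h and 24 h therefore cannot be compared with each other. Leaving out a library gave 654 to 858 genes between the doses at 24 h and 2604 to 3579 between the vehicle groups (4522), where 1 vehicle library remains and is assumed to vary like the other groups, with 2727 without 6 h replicate 1, 2638 without 24 h replicate 1 and 2604 without 24 h replicate 2. Over the 4 vehicle comparisons camera called 41 lists, and 39 to 43 with a library left out. It called 9 with an estimated correlation, and the cause of this loss was not tested. Fry called 91, but it does not compare a list with the other genes, so this count answers a different question. The correlation between doses was 0.979 at 6 h and 0.978 at 24 h over called genes, and 0.980 and 0.986 with the stricter filter. Libraries of the same number did not pair, with residual correlations of −0.0614 to 0.0690 over 36 pairs and 6 of 16 closest to their own number. With replicate number as a block, 13658, 14657, 13052 and 13711 genes changed against vehicle (3 and 10 µM at 6 h, then at 24 h), 5212 and 1270 between doses, 4285 between vehicle groups, and 10720 and 11784 between times. The treated minus vehicle share outside exons was 1.37 points over all pairs and 1.48 to 1.66 with a library left out.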

Other observations

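The lists in this part were fixed beforehand, and no further tests were chosen after results were seen. Members of the BCL2 family moved in opposite directions at 24 h. PMAIP1, which encodes the cell death protein NOXA, rose by 1.81 ± 0.08 at 3 µM and 1.99 ± 0.08 at 10 µM, HRK, another sensitiser of cell death, by 1.44 ± 0.21 and 1.81 ± 0.20, and BBC3 by 1.58 ± 0.07 and 1.60 ± 0.07, while the survival gene BCL2 changed by −0.90 ± 0.04 and −0.95 ± 0.04. Of 15 members, 7 rose and 7 fell at each dose, with 8 lower at 10 µM adjusted over the list alone (camera adjusted p = 0.212 and 0.20). The medians were −0.01 and −0.08 while the mean and the test were positive, and without scaling factors the medians were 0.09 and 0.03.

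Of 35 core spliceosome genes, 10 rose and 16 fell at 3 µM and 24 h, and 9 rose and 17 fell at 10 µM (adjusted p = 0.845 and 0.518). The U5 component PRPF8 changed by −1.15 ± 0.07 and −1.30 ± 0.07, and the U4/U6 component PRPF3 rose by 0.93 ± 0.03 and 1.03 ± 0.03. The list median turned from −0.02 to 0.08 and from −0.06 to 0.05 without scaling factors, with 17 higher at each dose and 7 and 9 lower. Among 17 mesenchymal genes, 7 rose and 9 fell at each dose at 24 h (adjusted p = 0.466 and 0.614), with the collagen-crosslinking enzyme LOX at 1.45 ± 0.07 and 1.92 ± 0.06 and the actin-binding TAGLN at −1.29 ± 0.04 and −1.56 ± 0.04. Its medians (−0.10 and −0.11) and test were negative while its means were 0.05 and 0.06, and without scaling factors the median at 3 µM was 0.00. Of 15 NRF2 targets 7 rose at each dose at 24 h, and 4 and 3 fell (adjusted p = 0.211 and 0.181). HMOX1, the haem-degrading enzyme, rose by 1.87 ± 0.36 and 1.89 ± 0.36.

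At 6 h the antiviral genes diverged. RSAD2 rose by 3.19 ± 0.30 at 3 µM and 2.82 ± 0.32 at 10 µM, and IFI27 by 2.55 ± 0.16 and 2.60 ± 0.16, whereas DDX58, the RNA sensor RIG-I, changed by −1.60 ± 0.07 and −1.48 ± 0.07. In the 6 h vehicle RSAD2 and IFI27 were at only 0.0681 and 0.233 CPM, and at 3 µM they reached 0.627 and 1.37. Both thus lay among the genes under 0.5 CPM in vehicle, many of which rose. Of 23 interferon response genes 7 rose and 7 fell at 3 µM, and 8 rose and 11 fell at 10 µM (adjusted p = 0.921 and 0.808), with medians of −0.07 and −0.27 and a negative test but means of 0.16 and 0.10. The aryl hydrocarbon receptor target CYP1A1 changed by −1.36 ± 0.14 and −1.52 ± 0.14, with 2 of 5 list members lower and none higher (adjusted p = 0.706 and 0.808).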
